A study of Mus musculus with 44 samples.

How the data were processed

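The samples were livers of male C57Bl/6J mice, an inbred laboratory strain, kept on a diet with 42% of its energy from fat. Per the labels, the animals received vehicle, Aroclor1260, PCB126 or both compounds by mouth at week 2 of a 12-week study. Aroclor1260 is a commercial mixture of highly chlorinated biphenyls, and PCB126 is a single dioxin-like congener that activates the aryl hydrocarbon receptor. The doses are not given in the sources used here. Liver RNA was immunoprecipitated with an antibody against N6-methyladenosine (m6A), the commonest internal modification of messenger RNA, in the assay known as MeRIP. There were 44 libraries, made up for each of the 4 treatments of 5 input libraries, 5 m6A immunoprecipitates and 1 immunoprecipitate with control IgG.

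Per the submitters' processing notes, the tools included bcl2fastq 2.20.0.422, FastQC 0.10.1, Trimmomatic and BWA 0.7.17 with the mouse build mm10, and their order and settings are not given in the sources used here. The deposited files were 8 peak lists titled as MeTPeak output, 1 for each treatment with the m6A libraries set against the input libraries and 1 with them set against the IgG library. The version and settings of that caller, and the gene annotation it used, are not given in the sources used here. Each list held 1 set of peaks for a whole treatment, with no value for any single animal. The spread between the 5 animals of a group therefore could not be measured, no test across animals was made, and no replicate could be left out or used as a block. The number of reads behind each list is unknown.

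Per the file headers, each peak came with a fold enrichment, a linear ratio of m6A immunoprecipitate over reference that the authors' caller computed. Each peak also had the authors' p-value and the log10 of that p-value and of its false discovery rate. The largest false discovery rate in any list was 0.0490. The fold enrichments and false discovery rates quoted are the authors' own values for single peaks and served to describe, rank or filter peaks within a list. A peak's span ran from its first to its last base, and its exonic blocks were those given in the file. Coordinates are those of mm10, counted from 1.

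Genes were given as Ensembl identifiers. They were named by position with the RefSeq gene table of GRCm38.p6, the same build, whose gene spans carry no strand and no exons. An identifier took the name of the RefSeq gene that held at least 80% of its exonic peak bases, and where several qualified, the name of the only protein-coding gene among them. Of the 1512 identifiers with a peak, 1398 were named and 114 were not. Identifiers with the same name were joined into 1 locus, which gave 1419 loci. At 88 loci more than 1 identifier was joined, at 67 of them from both strands, so at overlapping and antisense genes the name states the place and not the transcript. Members of near-identical families, such as Cyp2c50, Cyp4a12a, Mug1 and H2-Q6, share sequence and are uncertain.

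Peaks of 2 lists were called shared when their spans overlapped by at least 1 bp on the same chromosome and strand. Shares of peaks have Wilson 95% intervals, and the difference between 2 shares of the same control peaks has an interval from the discordant peaks. All intervals cover counting error only, since neighbouring peaks of a gene are not independent and animals are not represented. A locus was gained in an exposure when it had a peak in the exposed list and none in the control list, and lost in the opposite case. The lists called against input were the main ones, and counts against both references required the same call with input and with IgG. Overlaps of gained loci were set against the number for independent lists, which is the product of both counts over the loci in any of the 4 lists. That number also counts loci with a control peak, which cannot be gained, and this lowers it. It leaves out loci without a peak in any list, and this raises it, so the direction of its error is unknown. The overlaps were further set against 1000 randomisations of the table of loci by lists. In these, the number of loci per list and of lists per locus stayed as measured. The control list was shuffled along with the exposed lists and kept only its number of loci, so gains in a randomisation were counted against the shuffled control. In the data, 1 control list served every exposure, and it could not be split.

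The 27 gene lists were fixed before the data were examined, among them markers of the other liver cell types. The mitochondrially encoded genes were taken as all genes on chromosome MT, since the table's symbols do not carry the prefix the rule named. For lists with at least 5 members among the loci with a peak in any of the 8 lists, the number with a peak was placed among 10000 random lists of the same size drawn from those loci and matched on the length of the gene span in 5 bins. The percentile describes these lists and is no test across animals. Genes were named by a rule also fixed beforehand. It took the 10 gained and the 10 lost loci with the highest fold enrichment among those gained or lost against both references, filled up from those lost against input alone. It further took every fixed-list member gained or lost against both references, the 5 strongest control peaks, and the 10 strongest loci with a peak in the combination alone. Gene models without a symbol were counted and not named, and some genes that the rule took are not reported here.

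The alternatives planned beforehand were the IgG reference, a false discovery rate 10 times stricter, a fold enrichment of at least 2, and an equal number of the most enriched peaks from every list. The equal number was 506 per list against input and 2082 against IgG. Further alternatives required an overlap of 50% of the shorter span, a reciprocal overlap of 50% or an overlap of exonic blocks, counted any peak in the same gene as shared, merged overlapping peaks, or drew random lists from the loci of the input lists. The restriction to plus-strand peaks, the IgG reference together with an equal number of peaks, and the position of peaks along the gene span were added after the data were seen. The place of peaks in untranslated regions and coding sequence, and the m6A sequence motif, were not analysed here, since neither exon models nor a genome sequence were used here.

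All steps were run in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. The overlap step was tested on simulated data with 620 control peaks and recovered 100% of the peaks simulated as shared. Of 20 simulated sets of 4 independent lists with 1000 loci, 19 lay within the middle 95% of the randomisations, and a planted overlap lay at percentile 100. Of 200 gene lists drawn at random from 1000 simulated loci, 184 lay within the middle 95% of the random lists, and a list planted in the peak set lay at percentile 100.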

Results

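The series asked how exposure to polychlorinated biphenyls on a high-fat diet changes the m6A marks of liver RNA. Against input, the peak lists held 620 peaks at 255 loci in the control, 506 at 229 after Aroclor1260, 2178 at 688 after PCB126 and 2284 at 718 after the combination. Against IgG, they held 2091 peaks at 597 loci, 2082 at 601, 4129 at 1098 and 3683 at 994 in the same order. The PCB126 list was thus 3.51 times as long as the control list against input and 1.97 times against IgG. Each list was called for a whole treatment of 5 animals, so no value below has a replicate error, and differences between lists cannot be set against the spread between mice. Sequencing depth was unknown, and the length of a list depends on it.

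**Figure D1:**
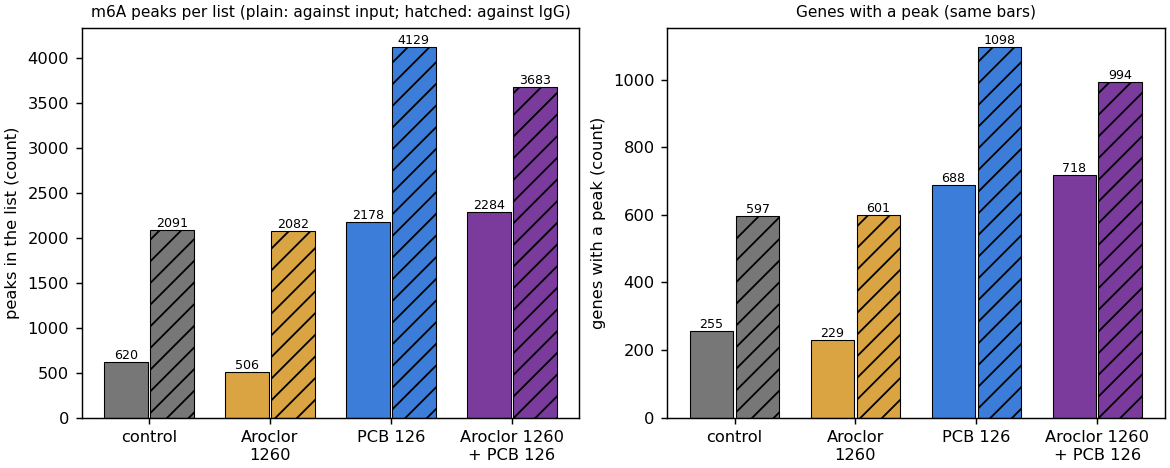
Number of m6A peaks (left) and of loci with a peak (right) in each of the 8 peak lists, with plain bars for lists called against input and hatched bars for lists called against IgG. Bars start at 0 and carry no error, since each is 1 list; the PCB126 and combination bars stand above the control bars with either reference.

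In control liver, the most enriched peak lay at Jund, which encodes a subunit of the AP-1 transcription factor. It spanned chromosome 8 from 70699047 to 70700322 and had a fold enrichment of 37.3. A minus-strand identifier at the same locus gave the next strongest peak, from 70699735 to 70700080, with a fold enrichment of 26.7. Gid8, a subunit of the GID ubiquitin ligase, followed with 25.2 on chromosome 2 from 180717846 to 180718339. Bmp2, a ligand that liver endothelial cells release, had 18.6 on chromosome 2 from 133561059 to 133561454. Ubtd1 had 18.0 on chromosome 19 from 42033804 to 42034001. All of these loci had a peak in each of the other 7 lists too, among 141 loci present in all 8. Median fold enrichment was 2.32 in the control list, with a median exonic width of 201 bp. Over the gene span, plus-strand control peaks had a median relative position of 0.775 (bootstrap 95% interval 0.718 to 0.803), where 1 is the high-coordinate end, and 46.1% lay in the last 20% of the span. Of the 17573 peaks in the 8 lists, 95.2% were on the plus strand, so the absence of a gene from these lists says little about its methylation.

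The choice of reference was examined within each treatment. Jund, Gid8, Bmp2 and Ubtd1 were found with either one, whereas the control locus Cpt1a, picked after its values were seen, had 9 peaks against IgG and 0 against input. Of the input-referenced peaks, 85.0% were also found against IgG in the control, 88.3% after Aroclor1260, 87.9% after PCB126 and 81.9% after the combination. In the opposite direction the shares were 24.4%, 21.0%, 47.0% and 52.9%. With a reciprocal overlap of 50%, the control shares were 55.0% and 16.5%, and by gene the shares in the opposite direction were 37.4% in the control and 33.7% after Aroclor1260.

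Aroclor1260 was first compared with the control. Against both references, 25 loci lost their peak and 14 gained one. The strongest lost locus was Tnfsf10, the gene of the death-receptor ligand TRAIL, whose control peak on chromosome 3 from 27335368 to 27335815 had a fold enrichment of 7.29. It was followed by Zcchc2 with 6.65, Epm2aip1 with 6.20, Purg with 6.00 and Lifr, the receptor of leukaemia inhibitory factor, with 5.80. Onecut2, a hepatic transcription factor, had 6 control peaks up to 5.79 and 0 after Aroclor1260. Dph7, Ppig, Zbtb10 and Kbtbd7 completed the 10 strongest, with control folds from 5.67 down to 4.60. Among the fixed lists, Slco1b2, which takes up bile acids and organic anions from blood, and the mitochondrial COX1 were lost, from control folds of 3.61 and 1.21.

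Of the 14 loci gained with Aroclor1260, the 10 with the highest fold are named. Znhit2 led with 3.86 on chromosome 19 from 6062127 to 6062324, before Tnfrsf1a, the main receptor of tumour necrosis factor, and Txnip, a glucose-responsive inhibitor of thioredoxin, each with 2.84. Mcl1, an inhibitor of apoptosis, had 2.21, and G6pc, the enzyme of the last step of glucose release, had 2.11. Ildr2 had 2.80, Zfp703 2.14, Cbx2 2.00, Mafg 1.75 and Anks1 1.68. The Ildr2 and Anks1 peaks belonged to minus-strand identifiers at those loci, as did the only Zfp703 peak after Aroclor1260 against input. Of the 620 control peaks, 50% (46.1 to 53.9%) were found after Aroclor1260, and 36.4% (32.3 to 40.6%) of the 506 Aroclor1260 peaks were absent from the control list. Against input alone, 65 loci were gained and 91 lost. Of the 184 gained peaks, 64.7% were already in the control list called against IgG, and of the 310 control peaks not found after Aroclor1260, 52.9% (47.3 to 58.4%) were in the Aroclor1260 list called against IgG. The counts moved to 182 gained and 178 lost with IgG as reference and to 35 gained with a fold of at least 2, and the absent share ran from 23.7% by gene to 56.7% with reciprocal overlap.

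PCB126 was compared with the control in the same way. Against both references, 214 loci gained a peak and 2 lost one. Pde4b, a phosphodiesterase that degrades cyclic AMP, had the highest fold enrichment of the whole list, 61.2 on chromosome 4 from 102605018 to 102605815. Arhgap29 followed with 40.7 on chromosome 3 from 122012137 to 122014861. Ccnt2, the cyclin T2 subunit of the elongation kinase P-TEFb, had 35.2, and Egfr, the epidermal growth factor receptor, had 3 peaks up to 23.9. Fem1a reached 19.5 with 6 peaks, Ctso 17.7, Tmem28 16.7, the transcriptional repressor gene Cic 16.6, Wac 15.9 and Znhit2 14.2.

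Fixed-list members gained with PCB126 included Jun, an immediate early gene, with 4 peaks up to 6.00, and G6pc, with 4 peaks up to 4.46. Fgb, which encodes the fibrinogen beta chain, had 4.10, and the mitochondrial rRNA mt-Rnr2 and ND6 had 3.92 and 3.37. Secisbp2, a factor for selenocysteine insertion, had 2.60. Pparg, a nuclear receptor of fat storage, had 1.86, and Mug1 had 1.82. The only symbol-bearing locus lost against both references was Kbtbd7, from a control fold of 4.60. Against input alone, the strongest lost locus was Apob, which encodes the structural protein of very-low-density lipoprotein, with 8 control peaks up to 13.9. PCB126 had 9 Apob peaks against IgG. The other named losses against input alone were Ppig with a control fold of 5.67, St6gal1 with 5.52, the mannose-binding lectin gene Mbl1 with 4.50, Cnnm2 with 4.29, Slco1b2 with 3.61, Ifngr1 with 2.67, Car3 with 2.31 and Otub2 with 2.29. None of these losses held against IgG. There, Ppig, Mbl1, Slco1b2 and Ifngr1 had peaks in both the control and PCB126, Cnnm2 and St6gal1 had 0 control peaks and 4 and 3 PCB126 peaks, and Car3 and Otub2 had a peak in neither.

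Of the 620 control peaks, 88.2% (85.5 to 90.5%) were found after PCB126, and 79.3% (77.5 to 80.9%) of the 2178 PCB126 peaks were absent from the control list. Gained peaks were less enriched than shared ones, with median folds of 2.25 and 4.17, and 41.0% of them were in the control list called against IgG. Against input alone, 451 loci were gained and 18 lost. With an equal number of peaks per list, 53.8% of PCB126 peaks were absent from the control, 210 loci were gained and 56 lost, and with IgG 68 were lost. With reciprocal overlap, 45.6% of control peaks were found.

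The combination of both compounds against the control gave 201 loci gained and 3 lost with both references. Arhgap29 led, with 26.1 over the span it had after PCB126. Ctso had 18.7, Egfr had 6 peaks up to 18.4, Cic 14.8 and Tmem28 14.2. The class I histocompatibility gene H2-Q6, which has near-identical relatives, had 13.8, Pakap had 13 peaks up to 13.2, and Tnrc6c, a partner of Argonaute in microRNA silencing, had 12.1. Zfp703 with 8.67 and Trim8 with 8.62 completed the 10 strongest.

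Fixed-list members gained with the combination against both references included the following. Scd1, the desaturase that makes oleate, had 9 peaks up to 4.12, and Abcg8, which exports sterols into bile, had 4.10. Cyp2c50, a cytochrome P450, had 3.12, Cyp4a12a, a male-biased fatty acid hydroxylase, had 3.45, and Nr0b2, the bile acid-induced repressor SHP, had 3.30. Gclm, a subunit of the enzyme that limits glutathione synthesis, had 2.83, the metallothionein gene Mt2 2.18 and the glutathione peroxidase gene Gpx1 1.56. Plasma protein genes gained were F9 with 4.04, Trf with 3.50, Mug1 with 3.21, Fgb with 2.46 and Ttr with 1.40. Jun had 4.83, Dmgdh 2.14, and the mitochondrial ND2, ND6 and mt-Rnr2 had 5.19, 4.70 and 4.70. The Dmgdh value belonged to a minus-strand identifier, 1 of 2 joined at that locus from both strands.

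Slf2, with a control fold of 3.11, and Foxq1, with 6 control peaks up to 2.23, were the symbol-bearing loci lost with the combination against both references. Against input alone, Ppara, the fatty acid-sensing receptor that drives fat oxidation, was lost from a control fold of 8.59, although it had 3 combination peaks against IgG. Lifr with 5.80, Ppig with 5.67, Dnajb12 with 4.79, Kbtbd7 with 4.60, Cnnm2 with 4.29, Zc3h4 with 3.94 and Tob1 with 3.85 were the other named losses against input. None of these held against IgG, where Cnnm2 had 0 control and 3 combination peaks and the others had peaks in both lists. Of the control peaks, 87.4% (84.6 to 89.8%) were found, and 79.6% (77.9 to 81.2%) of the 2284 combination peaks were absent from the control list. Against input alone, 480 loci were gained and 17 lost, and 44.0% of the gained peaks were in the control list called against IgG. With an equal number of peaks, 50.4% were absent, 191 loci were gained and 48 lost, and with IgG 75 were lost. With reciprocal overlap, 49.7% of control peaks were found.

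**Figure D2:**
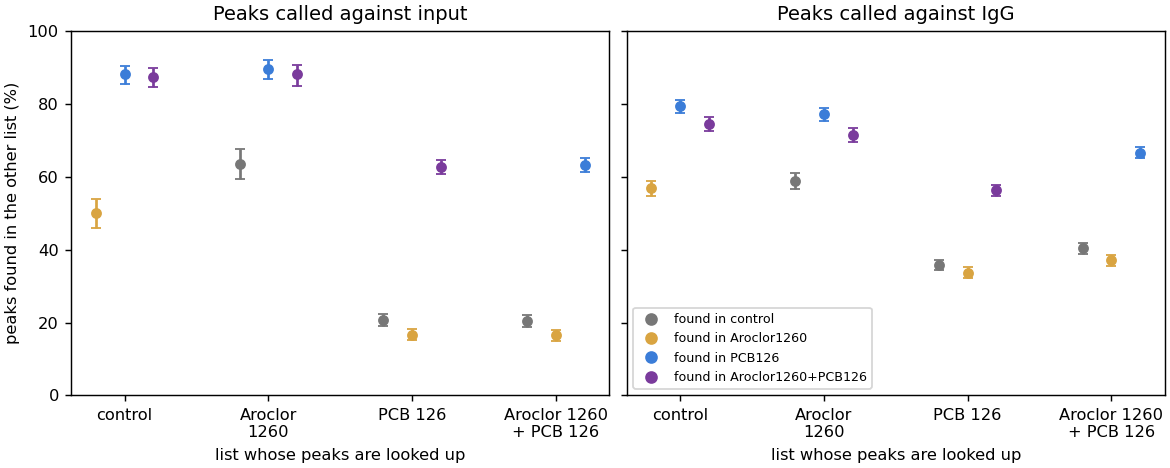
Percent of the peaks of each list (horizontal axis) that were found in each other list (colour), for lists called against input (left) and IgG (right); bars are Wilson 95% intervals, which cover counting error only. Against input, 50% of control peaks were found after Aroclor1260 and 88.2% after PCB126, while 20.7% of PCB126 peaks were found in the control.

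Aroclor1260 and PCB126 were then compared with each other. Loci gained with both compounds against both references numbered 8, and 5 of these were also gained with the combination, namely Ildr2, Mafg, Txnip, Zfp703 and Znhit2. These names state a shared place and not a shared transcript. Against input, the Aroclor1260 peaks at Ildr2 and Zfp703 belonged to minus-strand identifiers, and the strongest combination peak at Zfp703 to a plus-strand one. G6pc was gained with each compound against both references and had no peak in the control or in the combination with either reference. Cbx2, a Polycomb subunit, and Dap, both picked after their values were seen, had a peak after Aroclor1260 with both references and in no other treatment. Tnfsf10, Zcchc2, Epm2aip1, Purg, Onecut2, Dph7 and Zbtb10, lost with Aroclor1260, each had a peak after PCB126 and after the combination with both references. In all, 70 loci were lost with Aroclor1260 and kept in both other exposures against input, where the randomisations gave a mean of 70.0 (middle 95%, 64 to 75). Against IgG there were 113 such loci, at the upper bound of the randomisations, which gave 102.4 (92 to 113).

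The share of control peaks found was lower after Aroclor1260 than after PCB126, 50% against 88.2% (difference -38.2 percentage points, 95% interval -42.4 to -34.1). It rested on 249 control peaks found after PCB126 only and 12 found after Aroclor1260 only. The difference was -22.6 (-24.9 to -20.2) with IgG, -10.3 with reciprocal overlap and -7.71 (-13.1 to -2.31) with an equal number of peaks per list. Under IgG and an equal number of peaks together it was 0.720 (-1.97 to 3.41), an interval that includes 0. Against input, 50 loci were gained with both compounds, below the 57.2 (51 to 63) of the randomisations. The number for independent lists was 32.5. The direction of its error is unknown, since it counts loci with a control peak and leaves out loci without a peak, so no excess is read from it. The count was 122 with IgG, against 138.2 (126 to 149) in the randomisations. With a fold of at least 2 it was 31 against 32.7 (29 to 37). With an equal number of peaks it was 22 against 51.6 (43 to 60).

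The combination was finally compared with the single exposures. A peak in the combination alone, against both references, was found at 41 loci, 35 of them with a symbol. Cnst led with 4 peaks up to 6.00, the strongest on chromosome 1 from 179609898 to 179610545, before Ccm2, a scaffold protein of blood vessel integrity, with 5.85. ND2 had 5.19, Zfp62 5.14 and Galnt1, an enzyme that starts O-linked glycosylation, 4.23. Abcg8 and the coagulation factor gene F9 had 4.10 and 4.04, Igf1, the main growth factor the liver secretes, had 11 peaks up to 3.90, Pde3b had 3.84 and Nxt1 3.67. Loci gained with PCB126 and with the combination numbered 96 against both references, among them Arhgap29, Egfr, Ctso, Cic, Tmem28, Jun, Fgb and Mug1. Of these, Arhgap29, Egfr, Cic, Fgb and Mug1 also had 2, 10, 7, 2 and 4 peaks after Aroclor1260 against IgG. Ctso, Tmem28 and Jun had none after Aroclor1260 with either reference. Pde4b, Ccnt2, Fem1a and Secisbp2 had peaks after PCB126 with both references and none in the combination.

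Of the 2284 combination peaks, 63.3% (61.3 to 65.2%) were found after PCB126 and 16.5% (14.998 to 18.0%) after Aroclor1260. PCB126 without Aroclor1260 held 47.9% of them, Aroclor1260 without PCB126 1.09%, and both 15.4%. In none of the other 3 lists were 34.3% (32.4 to 36.3%), and these 783 peaks had a median fold of 1.86 against 2.79 for the rest. Against input, 291 loci were gained with PCB126 and with the combination, within the 288.5 (281 to 296) of the randomisations. The number for independent lists was 239.7. That number has an error of unknown direction for the same reasons, so no excess is read from it. Loci in the combination alone numbered 182, against 184.6 (179 to 191) in the randomisations. An equal number of peaks per list gave 116 against 100.3 (90 to 111) gained with both and 66 against 82.5 (74 to 92) in the combination alone, with 38.9% of peaks found after Aroclor1260 and 19.2% in no other list. The latter shares were 37.0% and 26.4% with IgG, 10.03% and 53.6% with reciprocal overlap and 27.5% and 20.8% by gene, and reciprocal overlap left 41.2% found after PCB126.

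**Figure D3:**
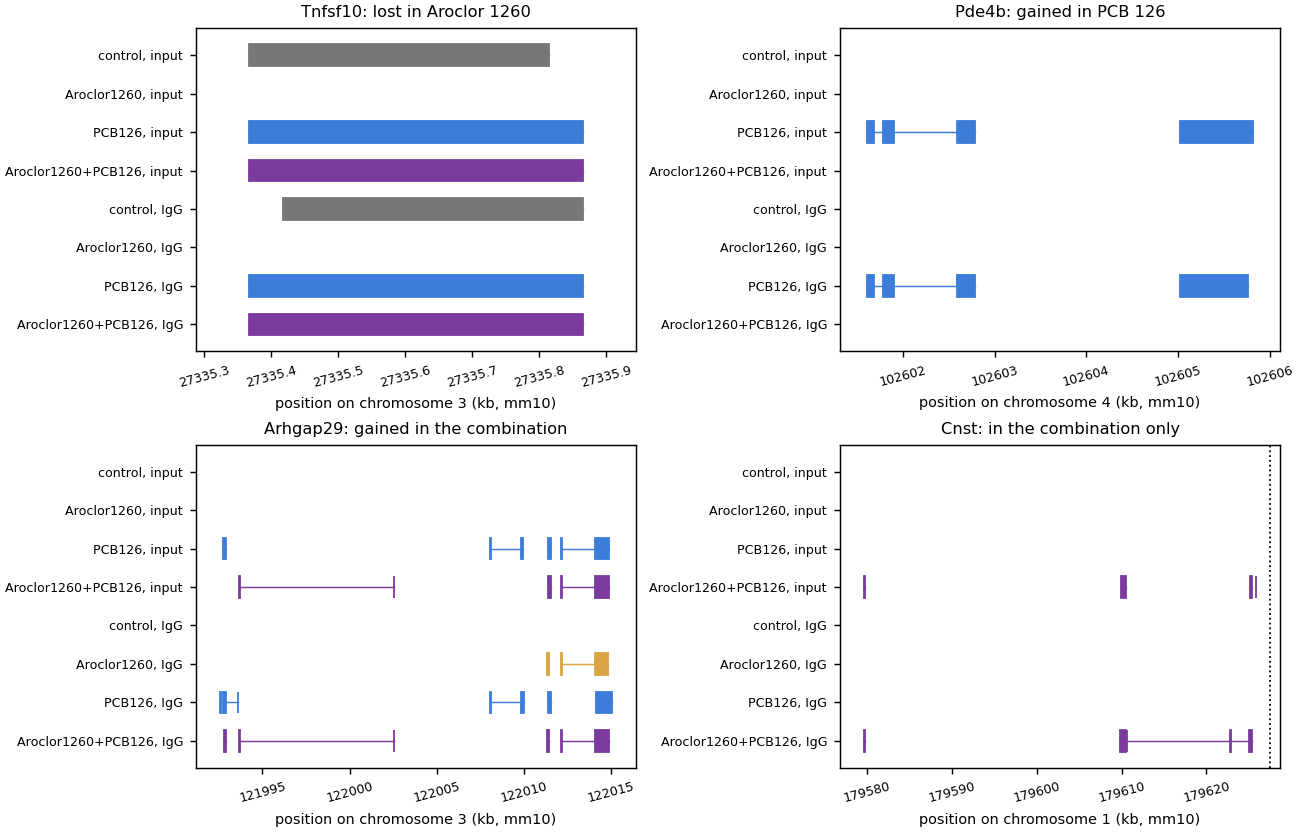
Peaks at Tnfsf10, Pde4b, Arhgap29 and Cnst in the 8 lists (rows), drawn to scale along the chromosome in kb of mm10; thick boxes are exonic blocks of a peak, thin lines join the blocks of 1 peak, and the dotted line is the RefSeq gene end. Tnfsf10 has no box in either Aroclor1260 list, Pde4b has boxes after PCB126 only, and Cnst has boxes in the combination only.

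The fixed gene lists were counted in each input-referenced list, and counts are given in the order control, Aroclor1260, PCB126 and combination, with "every list" standing for these 4. Targets of the aryl hydrocarbon receptor, through which PCB126 acts, had no peak in any of them. The only member with a peak in any list was Tiparp, in the combination against IgG with 2 peaks up to 13.0. Since 95.2% of all peaks lay on the plus strand, the absence of the other members says little about their methylation. The m6A machinery had 1, 0, 3 and 2 members of 26 (3, 2, 3 and 3 against IgG). Ythdf3, a cytoplasmic reader, was the control member. Zc3h13, a subunit of the writer complex, had 5 peaks up to 14.2 after PCB126, and Ythdc1, the nuclear reader, had 7 peaks up to 6.57. All 3 also had a peak in the control list called against IgG, so none was gained against both references.

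Among metabolic lists, fatty acid oxidation and targets of PPAR alpha had 3, 2, 3 and 6 members of 28, with Slc27a2 present in every list. Lipogenesis and triglyceride storage had 1, 2, 2 and 4 of 33, with Acsl1 in every list and Lpin2 after PCB126 and the combination. Cholesterol genes had 1, 0, 2 and 3 of 26, with Abcg8 in the combination only. Bile acid genes had 2, 2, 3 and 6 of 19, with Akr1d1 in every list. Amino acid catabolism and the urea cycle had 2, 1, 2 and 5 of 29, with Glud1 in the combination only. Methionine and one-carbon metabolism had 0, 0, 1 and 2 of 25, led by Chdh. Against IgG, the counts of these lists were 6, 6, 8 and 8, then 5, 6, 5 and 6, then 1, 3, 3 and 3, then 5, 5, 7 and 7, then 5, 4, 6 and 4, and 1, 2, 1 and 2, and Lpin2, Glud1 and Chdh had 9, 3 and 6 control peaks. Glucose metabolism and insulin signalling had 2, 4, 3 and 3 of 19, with Foxo1 and Ppp1r3b in every list, and 4, 5, 7 and 3 against IgG. Targets of the xenobiotic receptors CAR and PXR had 0, 2, 2 and 4 of 27, with Por and Cyp2c29 in all 3 exposures. Against IgG the counts were 2, 2, 4 and 3, and both genes also had control peaks there, 7 and 4. NRF2 and oxidative stress genes had 0, 0, 1 and 3 of 20 and against IgG 1, 1, 4 and 6, and selenoproteins 0, 0, 1 and 1 of 18 and against IgG 0, 2, 2 and 4.

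Secreted plasma proteins had 6, 6, 10 and 14 members of 40 (11, 11, 12 and 14 against IgG), with Fga, Kng1, Cp, F10 and Serpinc1 in every list. Apolipoproteins and lipoprotein handling had 6, 3, 6 and 7 of 18, and 8, 8, 7 and 6 against IgG. Apoa1, Apoa5 and Apoe, which encode carriers of plasma lipids, were in every list, and Apob was in the control and the combination against input and in every treatment against IgG. The control count stood at percentile 99.98 of the random lists and the combination count at 97.49, or at 99.7 and 89.2 with random lists drawn from the loci of the input lists, while the plasma proteins of the combination stood at 97.7 and the glucose genes of Aroclor1260 at 98.9. Immediate early genes had 4, 5, 6 and 6 of 21 (5, 5, 6 and 5 against IgG), with Jund, Klf2, Klf9 and Myc in every list, at percentiles 99.3, 99.97, 99.1 and 99.1. Drawn from the loci of the input lists alone, those percentiles were 95.8, 99.6, 87.3 and 86.7. The unfolded protein response had 2, 2, 5 and 5 of 20 (5, 4, 5 and 5 against IgG), where Hspa5 and Pdia3 were in every list and Atf4, Xbp1 and Herpud1 joined after PCB126 and the combination. Hepatocyte transcription factors and nuclear receptors had 2, 2, 5 and 5 of 26 (4, 4, 5 and 4 against IgG), where Cebpa and Cebpb were in every list and Hnf4a, Rxra and Pparg joined. Those PCB126 and combination counts stood at percentiles from 98.1 to 98.5, and from 83.2 to 86.1 with loci of the input lists alone. The percentiles among loci of all 8 lists that are not given here ran from 5.69 to 95.8. Of the joining genes, only Pparg had no peak in the control list called against IgG.

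Acute phase and inflammation genes had 3, 3, 3 and 3 members of 25 (3, 4, 5 and 5 against IgG), with Crp and Hp in every list. Circadian clock genes had 2, 1, 3 and 2 of 19 (2, 2, 4 and 4 against IgG), with Bhlhe40 in every list. Sex-biased liver genes had 0, 0, 0 and 2 of 21 (0, 2, 3 and 2 against IgG), the members being Cyp4a12a and Cyp2a5. Mitochondrially encoded genes had 2, 1, 4 and 6 of 37 (3, 1, 4 and 7 against IgG), with ND4 in every list. Ribosomal proteins had none of 83 in these lists, and Rpl4 and Rpl8 appeared against IgG. Among markers of other liver cells, the endothelial list had 3 of 16 in every treatment (3, 2, 3 and 3 against IgG), namely Ptprb, Eng and Bmp2. The stellate cell and matrix list had Dcn alone of 18 and the Kupffer cell and macrophage list Cd5l alone of 16, each in the combination against input, and both also in the control against IgG. Cholangiocyte markers had none of 8, with Spp1 after PCB126 against IgG, and lymphocyte, neutrophil and erythroid markers had none of 25 in any list. Over all fixed lists, 42, 39, 68 and 92 members had a peak, and with IgG 81, 82, 105 and 106. Taking an equal number of peaks per list, they were 38, 39, 41 and 49.

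**Figure D4:**
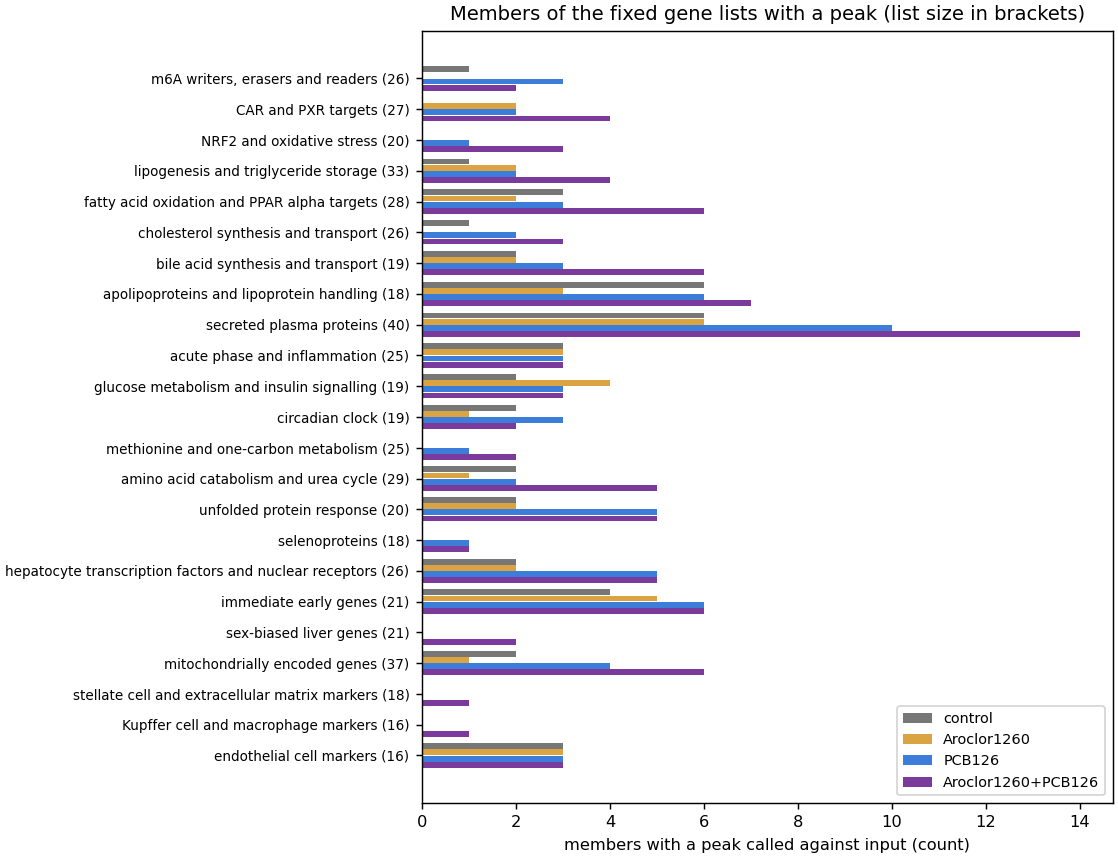
Number of members of each fixed gene list with a peak called against input (horizontal axis), by treatment (bar colour), for lists with at least 1 such member; the size of each list is in brackets and bars start at 0. Secreted plasma proteins run from 6 members in the control to 14 in the combination, and endothelial markers stay at 3.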

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

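The peak lists hold no value per animal, so leaving out each replicate was not run, and neither were the alternatives on peak position in transcripts and on the sequence motif. No paired analysis was possible because each list pools the 5 replicates of a treatment. Depth is unknown, and a shorter list can reflect shallower sequencing. Of the values that answer a comparison, recomputed under each alternative, 122 stayed within their interval or within 1.5 times their count, 96 moved further and 1 changed sign. The change of sign was in the Aroclor1260 minus PCB126 difference with IgG and an equal number of peaks together, 0.720 points (-1.97 to 3.41), a combination of 2 choices that was tried after seeing the data and for this result only. The stricter false discovery rate (30 values), overlap of exonic blocks (18), merged peaks (8) and the restriction to plus-strand peaks (26, chosen after seeing the data) moved none of them that far. These settings left most peaks or overlaps as they were, so they had little scope to move a value. Of the 620 control peaks against input, 600 passed the stricter rate, 608 remained after merging and 569 were on the plus strand. Where values moved, the cause was not tested, except that an equal number of peaks removes most of the longer lists by construction. In what follows, values are in the order Aroclor1260, PCB126 and combination unless stated.

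With IgG, the control peaks found were 56.8, 79.4 and 74.6%, and the exposed peaks absent from the control were 41.1, 64.2 and 59.7%. The Aroclor1260 minus PCB126 difference was -22.6 points. Combination peaks were found after PCB126 in 66.6%, after Aroclor1260 in 37.0% and in no other list in 26.4%. Aroclor1260 gained 182 loci and lost 178, PCB126 lost 68, the combination lost 75, and 122 were gained with both compounds. Fixed-list members were 81 in the control, 82 after Aroclor1260 and 105 after PCB126.

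Taking an equal number of peaks per list, the control peaks found were 54.2, 61.9 and 60.7%, and 42.9, 53.8 and 50.4% of exposed peaks were absent from the control. The difference was -7.71 points. Combination peaks were found after PCB126 in 70.8%, after Aroclor1260 in 38.9% and in no other list in 19.2%. PCB126 gained 210 loci and lost 56, the combination gained 191 and lost 48, 22 were gained with both compounds, and 66 were in the combination alone. Fixed-list members were 41 after PCB126 and 49 after the combination.

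With a fold of at least 2, 25.4% of Aroclor1260 peaks were absent from the control, and control peaks were found in 92.1% after PCB126 and 93.1% after the combination. Combination peaks were found after PCB126 in 66.2%. Aroclor1260 gained 35 loci, and 31 were gained with both compounds. Lists against input held 392 peaks in the control, 284 after Aroclor1260 and 1507 after the combination. Peaks against input were found against IgG in 90.3% in the control and 92.6, 92.1 and 86.9% in the exposures, and the reverse in 17.6, 41.8 and 47.5% in the exposures.

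With reciprocal overlap, the control peaks found were 35.3, 45.6 and 49.7%, and 56.7, 86.9 and 86.4% of exposed peaks were absent. The difference was -10.3 points. Combination peaks were found after PCB126 in 41.2%, after Aroclor1260 in 10.03% and in no other list in 53.6%. Peaks against input were found against IgG in 55.0% in the control and 58.3, 62.7 and 60.2% in the exposures, and the reverse in 16.5%, then 14.2, 33.1 and 37.4%.

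With any peak in the same gene, the control peaks found were 64.0, 93.9 and 95.5%, and 23.7, 68.6 and 68.1% of exposed peaks were absent. The difference was -29.8 points. Combination peaks were found after PCB126 in 76.9%, after Aroclor1260 in 27.5% and in no other list in 20.8%. Peaks against input were found against IgG in 93.4% in the control and 96.0, 96.9 and 96.1% in the exposures, and the reverse in 37.4%, then 33.7, 62.0 and 67.9%.

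With overlap of 50% of the shorter span, combination peaks were found after PCB126 in 60.7% and in no other list in 36.5%. Peaks against input were found against IgG in 80.3% in the control and 85.0, 85.1 and 79.2% in the exposures, and the reverse in 45.0% after PCB126 and 50.7% after the combination.

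Of the named genes, 10 of 10 gained with Aroclor1260, 19 of 19 with PCB126 and 29 of 29 with the combination were gained with IgG too, by the rule that chose them. Some of these gains against input were lost under other settings. With the stricter false discovery rate the counts were 7, 19 and 29, where G6pc, Cbx2 and Mafg dropped out for Aroclor1260. They were 8, 17 and 27 with a fold of at least 2, 10, 13 and 17 for an equal number of peaks, and 7, 16 and 24 with plus-strand peaks only, a setting chosen after seeing the data. With IgG, 12 of 12 named losses held for Aroclor1260, 1 of 10 for PCB126 and 2 of 10 for the combination. These counts were set by the rule too. It took losses against both references first and filled up with losses against input alone, which cannot hold with IgG.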

Other observations

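The gene families below, the tests of shared reads, of a deficit in 1 treatment, of the input libraries and of the reference library, and the position of peaks along genes were chosen after the data were seen. Among 9 symbol families with at least 8 members, symbols beginning with Zfp, which name zinc finger proteins and mostly transcription factors, were the most numerous. Of 25 Zfp loci with a peak in any list, 4 had one in the control against input, 4 after Aroclor1260, 20 after PCB126 and 14 after the combination. Against IgG the counts were 8, 8, 23 and 17. After PCB126, 11 of them were gained against both references, namely Zfp1, Zfp148, Zfp280d, Zfp518a, Zfp563, Zfp574, Zfp622, Zfp623, Zfp638, Zfp646 and Zfp703. Random lists of loci of the same size, matched on length, held a mean of 3.84 and at most 10 such gains. Of the 9 families, only Zfp lay above every random list. The family was singled out on the same data, and random lists of loci do not measure the spread between animals. After the combination 8 Zfp loci were gained against both references, and after Aroclor1260 only Zfp703. The related Zbtb family had Zbtb1, Zbtb11 and Zbtb41 gained after PCB126, 3 of 8, and none after the combination. Cytochrome P450 genes, with symbols beginning with Cyp, had 2, 2, 2 and 8 of 12 loci in the same order against input, and with 3 gained against both references after the combination and 0 after PCB126. That difference did not carry over to IgG, where PCB126 had 7 and the combination 8.

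Loci with a peak in all 8 lists numbered 141. Ordered by the lowest of their 8 strongest folds, Jund led with 24.9 at the least, before Gid8 with 21.9, Agtr1a, the main receptor of angiotensin, with 16.9, Ubtd1 with 16.1, Bmp2 with 15.7, and Bhlhe40, a repressor tied to the circadian clock, with 14.3. Rnf144b, Fga, Arf6 and Hs6st1 followed, each at 10.9 or more. Malat1, an abundant nuclear long noncoding RNA, and Spry1, an inhibitor of receptor tyrosine kinase signalling, were among the 25 loci lost with Aroclor1260 against both references, and both were picked for mention after their values were seen.

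The PCB126 list was far longer than the control list. The same peak set called with more sensitivity would leave few of the most significant PCB126 peaks outside the control list. Of those in the lowest 20% of false discovery rates, 68.5% (64.0 to 72.7%) were absent from it and 33.6% from both control lists. For Aroclor1260, whose list was shorter than the control list, these shares were 40.6% and 8.91%. A share of 40.6% thus arose without a longer list, and only the difference between both exposures bears on sensitivity. The PCB126 share depends on the order and the reference. In the 20% of PCB126 peaks with the highest fold it was 50.8% (46.1 to 55.5%), and against IgG it was 53.3% by false discovery rate and 39.4% by fold. The Aroclor1260 shares in the same order were 12.9, 40.1 and 21.4%. The peaks with the lowest false discovery rates were not the most enriched, with a median fold of 2.44. A difference in the input libraries alone was argued against by the lists called against IgG, where PCB126 still had 1.97 times as many peaks. The bound set beforehand against sensitivity, 50% or more absent among the lowest false discovery rates, was passed against input. With the order by fold or with IgG, the interval did not lie above 50%. Against IgG it was 49.9 to 56.7% by false discovery rate and 36.1 to 42.8% by fold. The values therefore do not decide whether sensitivity is the whole explanation. Sensitivity may account for at least part of the pattern, since the peaks with the highest fold were absent less often. Further, 41.0% of the gained peaks were in the control list called against IgG. A biological effect of PCB126 was not tested, and it cannot be told apart from a difference in depth or immunoprecipitation between the groups, since depth is unknown and each treatment has 1 list.

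Peaks on the minus strand were few in every list. If plus had been written as a default, peaks called plus would lie toward both ends of their genes alike, but their median relative position in the input lists was 0.784 (0.775 to 0.793), close to the 3' end of plus-strand genes. The highest minus-strand share of any list was 9.09% with an upper limit of 11.9%, which restates the pattern and excludes no explanation of it. Reads shared with overlapping plus-strand genes remain a possible explanation for some minus-strand calls, since 40.5% (37.3 to 43.9%) of the 841 minus-strand peaks lay over a plus-strand peak of the same list, a share between the bounds set for and against it. No biological explanation was tested.

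The combination list held more hepatocyte metabolic genes than the PCB126 list, 50 against 32 of the 237 members of 9 fixed lists. Of these, 20 were in the combination list and not in the PCB126 list, and 2 the reverse. The control and Aroclor1260 lists were not considered in this count. With IgG as reference the difference in members was -3, with 53 against 56, so the reference library is a candidate explanation for it. Weakly enriched background of abundant transcripts could not be excluded, since the 69 peaks of the 20 genes had a median fold of 2.12 (1.83 to 2.46) against 2.40 for the whole list. An interaction of both compounds was not tested, as the lists hold no values per animal.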
